A study of Arabidopsis thaliana with 3 samples.

How the data were processed

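The 3 libraries were 1 of mixed-stage inflorescences and 2 of unopened flower buds of Col-0. Per the labels' protocols, total RNA was extracted with Trizol or a plant RNA reagent, small RNA libraries were built, and single-end reads were taken on an Illumina GAIIx or HiSeq instrument; which instrument served which library is not given in the sources used here. The deposited values are counts: each file lists distinct sequences with the whole-number read count of each, with no scaling, alignment or annotation. Adapter trimming, length limits, quality filters and the authors' genome build are not given in the sources used here. Sequences were 18 to 34 nt long in the inflorescence and bud 2 and 18 to 30 nt in bud 1. The libraries held 26084301, 11808921 and 24688934 reads. Sequences seen once made up 32.5%, 23.9% and 15.4% of reads in the inflorescence, bud 1 and bud 2.

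Every sequence of 18 to 28 nt was matched without mismatches to both strands of the TAIR10.1 reference with a hash search written in Python 3.11.15 with numpy 2.4.6 and numba 0.67.0. Matched reads numbered 15468831, 10129717 and 19190684. Each sequence took 1 class in a fixed order from ribosomal, transfer, small nuclear and nucleolar RNA and organellar genomes to MIR, TAS, pseudogene, protein-coding, other noncoding and intergenic sequence. Nuclear ribosomal DNA was taken as the annotated 18S and 5.8S genes with 2 kb upstream and 4 kb downstream. Mature miRNAs were counted as exact sequences of the annotation, 350 distinct sequences, and summed by family, with miR156 and miR157 kept apart. Reads of 21 and 22 nt and of 24 nt that matched at 1 place were counted by midpoint, on either strand, over genes other than MIR, ribosomal, transfer, small nuclear and nucleolar RNA genes, and those of 24 nt also in 1-kb bins. Bins were gene-poor where protein-coding genes covered under 40% of their 500-kb window, which held for 21.4% of bins. Of 24-nt reads without structural RNA, 74.0%, 79.4% and 79.5% matched at 1 place. The annotation does not mark transposable elements as such, so siRNAs were not assigned to them.

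Features with at least 10 reads in 1 library were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, scaled by TMM, with Benjamini-Hochberg adjustment and a threshold of 0.05. The model had 1 residual degree of freedom: the spread came from the 2 bud libraries, moderated across features, and the inflorescence library was assumed to vary like them. Group sizes, replicates in accession order, designs, lists and alternatives were fixed before the data were examined. The lists were 6 of miRNA families (floral timing and development, nutrient and copper, silencing machinery, triggers of tasiRNAs and phasiRNAs, pollen-associated, recently evolved) and 3 of loci (TAS loci, phasiRNA-producing PPR genes, other phasiRNA genes). No set test was run. The rule for named features took the 10 mature miRNAs with the highest mean RPM, up to 10 called miRNAs in each direction, the listed families and loci, the 5 called genes of each gene fit with the largest fold change in each direction, and the 3 such bins, each with both buds on the same side and at least 100 reads in 1 library. A fold change against 0 reads was bounded with a floor of 3 counts in the inflorescence library. Shares have exact Clopper-Pearson 95% intervals. Standard errors are the edgeR fold change divided by the square root of its F statistic. The phasing register at TAS loci used both strands with a 2-nt offset for the reverse strand. The leading register without phasing was drawn at random for each locus and library, with each read placed independently. TAS3C is the gene annotated as TASIR-ARF.

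The test was run on simulated counts with the means, depths and spread of these libraries. Of genes changed 16-fold upward, 98% were recovered for 24-nt sRNAs, 64% for 21- and 22-nt sRNAs and 100% of bins. For 16-fold decreases the shares were 82%, 8% and 56%, and for 4-fold increases 48%, 4% and 16%. Among mature miRNAs and families 0 of 10 were recovered at 4-fold or 16-fold. Unchanged features called numbered 7 for 24-nt genes, 9 for bins and 0 for the others.

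Alternatives tried were DESeq2 1.42.0, scaling by all genome-matched reads, no filter on low counts, a minimum of 50 reads, leaving out each bud library, reads within 2 nt of the mature ends, reads at up to 50 places divided among them, 5-kb bins, and for shares genome-matched reads, structural RNA removed, distinct sequences and sequences seen at least 2 times. Scaling by matched reads without structural RNA, weighting of reads to equal end-base composition and removal of a GC trend (lowess, span 0.3) were added after the data were seen. Unmatched reads were compared with the genome, allowing up to 2 mismatches, with bwa 0.7.19-r1273 on 100000 reads per library and length. Tables and figures used pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.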

Results

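Small RNAs were sequenced from wild-type Arabidopsis thaliana of the Col-0 accession, the reference strain of the species. The series compared mixed-stage inflorescences, the flowering shoot tips with buds and open flowers of several ages, with unopened flower buds. It held 3 libraries: 1 from mixed inflorescences and 2 from unopened buds, called bud 1 and bud 2 here. The mixed inflorescence library held 26084301 reads of 9966894 distinct sequences. Bud 1 held 11808921 reads and bud 2 held 24688934, so that bud 1 had the lowest depth. Exact matches to the TAIR10.1 genome accounted for 60.1% of the inflorescence reads of 18 to 28 nt, 85.9% in bud 1 and 81.8% in bud 2. The inflorescence group had no replicate, and the gap between the 2 bud libraries was the only measure of spread. Nothing in the labels says that the bud libraries came from separate plants, so p-values measure only the spread between these libraries, which may be technical. Intervals given here cover counting error only, and those of the length and annotation shares were at most 0.101 percentage points wide.

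The first question was how the sizes and genomic origins of floral small RNAs compared between the tissues. The 24-nt class, which holds the heterochromatic siRNAs of the RNA polymerase IV pathway, was the largest in every library, with 45.1% of reads of 18 to 28 nt in the inflorescence, 43.9% in bud 1 and 36.4% in bud 2. The 21-nt class, which holds most miRNAs and tasiRNAs, took 20.6%, 13.8% and 17.0% in the same order. Among genome-matched reads without structural and organellar RNA the 24-nt share was 48.7% in the inflorescence, below both bud values of 58.9% and 55.1%. Among all reads it lay above both. Matching alone already put it between the buds, at 46.1% against 46.6% in bud 1 and 37.2% in bud 2, so removal of structural RNA was not the only step that moved it. Over distinct sequences it also lay between them, at 49.2% against 49.5% and 46.2%. Fragments of ribosomal RNA made up 4.47% of matched reads in the inflorescence, 23.3% in bud 1 and 35.9% in bud 2. Transfer RNA fragments took 1.34%, 1.69% and 1.63%, small nuclear and nucleolar RNA 0.104%, 0.129% and 0.536%, chloroplast sequences 0.913%, 0.227% and 1.21%, and mitochondrial sequences 0.507%, 0.542% and 1.15%. MIR genes accounted for 22.02% of matched reads in the inflorescence, against 9.28% and 12.8% in the buds. Loci annotated as pseudogenes, many of which are relics of transposable elements, took 17.7% in the inflorescence and 11.3% and 7.74% in the buds, while TAS loci took 0.221% against 0.620% and 0.522%. No test was run on these shares, and the rRNA share differed by more than 10 percentage points between the buds themselves.

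**Figure D1:**
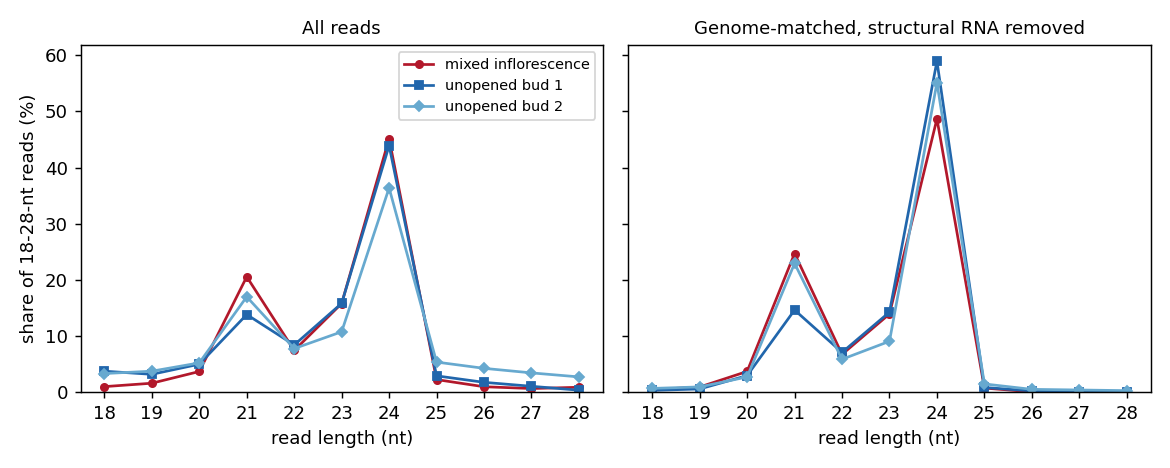
Share of reads of each length from 18 to 28 nt (percent, vertical axis) against read length in nt, with 1 line per library, for all reads (left) and for genome-matched reads without structural and organellar RNA (right). The 24-nt peak is the highest in every library, and on the right it reaches 48.7% in the mixed inflorescence against 58.9% and 55.1% in the buds.

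First bases also parted the libraries. Adenine opened 40.6% of 24-nt reads without structural RNA in the inflorescence, against 57.9% in bud 1 and 59.6% in bud 2, and guanine opened 27.5% against 11.5% and 12.3%. Among 21-nt reads outside MIR genes, guanine opened 32.2% in the inflorescence and 12.4% and 13.2% in the buds, whereas uracil, the 5′ base preferred by ARGONAUTE1, opened 23.6% against 36.4% and 36.1%. Each of these inflorescence shares lay outside the bud values by more than the gap between the buds. The guanine excess was not particular to these classes, since it was present at every length from 18 to 28 nt. At 18 nt guanine opened 41.3% against 17.7% in bud 1 and 19.9% in bud 2, and at 22 nt 31.6% against 13.5% and 14.0%.

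The bud libraries were compared before they were used as replicates. Counts of 24-nt sRNAs per gene gave a Pearson r of 0.902 across 6921 genes on the log2 scale, those of 21- and 22-nt sRNAs per gene 0.777 across 5984 genes, and mature miRNAs 0.558 across 191 sequences, where features are not independent replicates. The median miRNA differed 5.33-fold between the buds after scaling, and 71 of 191 miRNAs (37.2%) differed by more than 10-fold, compared with 82 of 6921 genes (1.18%) for 24-nt sRNAs. A chi-square test of the counts put every pair of libraries far beyond sampling noise, so no library was present under 2 names.

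**Figure D2:**
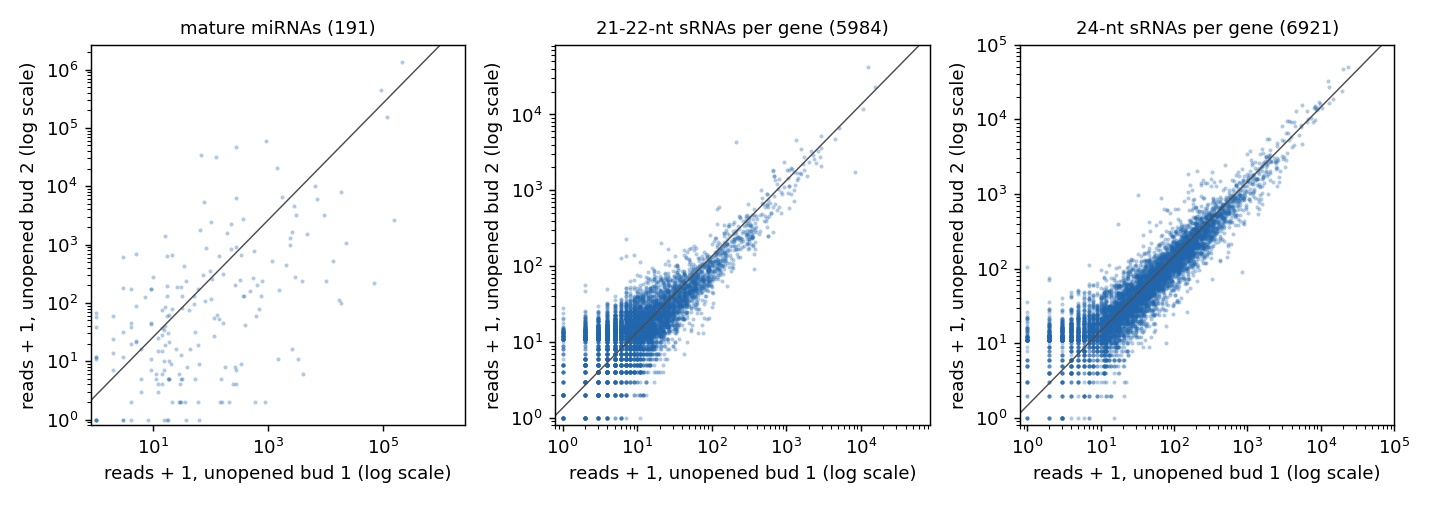
Reads plus 1 in bud 1 (horizontal, log scale) against bud 2 (vertical, log scale) for 191 mature miRNAs, 5984 genes with 21- and 22-nt sRNAs and 6921 genes with 24-nt sRNAs, 1 point per feature. The line marks equal shares of the counted reads, and the miRNAs scatter about it far more widely than the 24-nt sRNAs.

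The second comparison asked which miRNAs differed between mixed inflorescences and unopened buds. The miR172 family, which represses APETALA2-like regulators of flowering and floral organ identity, made up 60.7% of mature miRNA reads in the inflorescence, but 10.7% in bud 1. Its abundance in RPM, relative to the genome-matched reads of each library, was 121370 in the inflorescence, 8884 in bud 1 and 27.7 in bud 2. The miR169 family, which targets NF-YA transcription factors, stood at 42653, 826 and 1.35, and miR394, which targets the F-box gene LCR, at 12481, 260.3 and 84.6. In both buds the leading family was miR166, a regulator of the HD-ZIP III genes of organ polarity, with 25.7% of mature miRNA reads in bud 1 and 60.4% in bud 2, against 3.72% in the inflorescence. miR165, which targets the same genes, held 20.02% in bud 2 and 11.1% in bud 1, where miR167 and miR158 lay above it with 19.01% and 13.8%, against 1.998% in the inflorescence. The miR158 family stood at 59.5 RPM in the inflorescence, 11475 in bud 1 and 7949 in bud 2.

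None of the 191 mature miRNAs and none of the 109 families differed past an adjusted p of 0.05 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Before adjustment 8 miRNAs and 4 families had a p below 0.05, and DESeq2 called 28 miRNAs (13 higher, 15 lower) and 8 families (4 higher, 4 lower). The most abundant sequence, miR172a/miR172b-3p (AGAATCTTGATGATGCTGCAT, chromosome 2, 11942918 to 11942938), had a log2 fold change of 6.02 with a standard error of 6.78 (edgeR adjusted p = 0.692), of 13.04 without bud 1 and of 5.07 without bud 2. The next, shared by miR166a-3p and its paralogs (TCGGACCAGGCTTCATTCCCC, chromosome 2, 19176241 to 19176261), had −2.70 with a standard error of 7.19. Of the 10 most abundant sequences, miR172a/miR172b-3p, both leading miR169 sequences, miR394a/miR394b-5p and miR158a-3p passed in DESeq2, whereas those of miR165, miR166, miR167, miR156 and miR172c/miR172d did not. On simulated counts with the spread of these libraries, edgeR recovered 0 of 10 miRNAs changed 16-fold in either direction, so differences of that size were not detectable with that test here. Sequences shared by several MIR genes, such as those of miR166 and miR169, cannot be assigned to 1 of them.

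**Figure D3:**
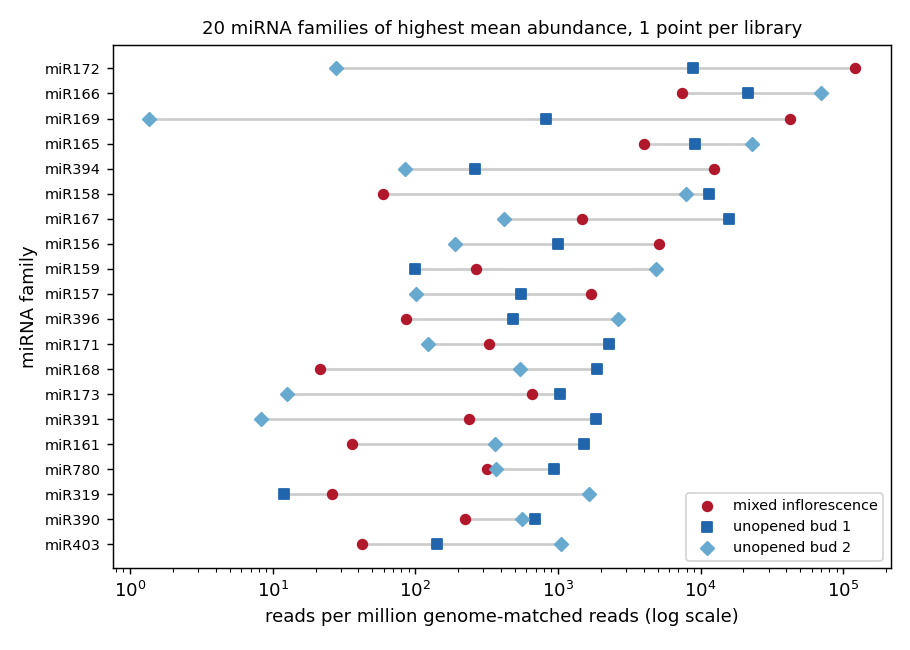
Abundance in RPM relative to genome-matched reads (horizontal, log scale) of the 20 miRNA families with the highest mean, 1 point per library, joined by a grey line. miR172 spans from 27.7 in bud 2 to 121370 in the mixed inflorescence, with bud 1 at 8884 between them.

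Lists of families fixed beforehand were described in the same units. Of 16 families of floral timing and development, all were measured and 0 passed, over all families or adjusted over the list alone, with 2 unadjusted p below 0.05 in edgeR and 3 calls, all higher, in DESeq2. Within it miR156 and miR157, which repress the SPL genes of phase change, stood at 5116 and 1702 RPM in the inflorescence, above 998 and 552 in bud 1 and 189.0 and 101 in bud 2. The GAMYB regulator miR159 and the TCP regulator miR319 lay between the buds, with 268 and 26.2 in the inflorescence, 98.9 and 12.0 in bud 1, and 4900 and 1652 in bud 2. miR167, which targets ARF6 and ARF8, stood at 1481 against 15767 and 421, and miR396, which targets the growth-regulating factors, at 85.5 against 485 and 2655. After scaling with TMM (trimmed mean of M-values), miR165, miR166, miR390 and miR393 lay between the buds, whereas in RPM they lay below both, and miR164 lay above both buds, whereas in RPM it lay between them. Over all lists the position against the buds differed between these scales for 20 of 76 families.

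The smaller lists held 0 calls as well, over all families and adjusted over the list alone. Among regulators of the silencing machinery, with 3 of 3 families measured, miR168, which targets ARGONAUTE1, stood at 21.5 RPM in the inflorescence and at 1871 and 540.0 in the buds, and miR403, which targets ARGONAUTE2, at 42.4 against 143 and 1059. The DCL1 regulator miR162 differed least, with 352, 278 and 244. Of 8 nutrient and copper families 7 were measured, among them miR398 at 2.46, 2.17 and 39.9 and miR399 at 16.4, 34.7 and 37.2. Of 7 families that trigger secondary siRNAs 6 were measured, with miR173 at 658 against 1040 and 12.7, and miR161 at 35.9 against 1516 and 364. Of 5 pollen-associated families, listed because open flowers hold mature pollen, 4 were measured. In RPM miR845 stood at 5.95 against 13.9 and 25.3 and miR775 at 1.29 against 113 and 27.3. The most abundant, miR780, stood at 318 against 943 and 365, and miR447 at 5.43 against 78.9 and 132. After TMM scaling miR780 lay above both buds, 2 families below and 1 between them. Of 70 families described as recently evolved 51 were measured, and 31 of them lay below both buds after TMM scaling and 9 above. Over all 109 families 47 lay below both buds and 28 above on that scale. In RPM the position of 11 of the 51 was another. Unadjusted p below 0.05 in edgeR numbered 1 in the nutrient list, 1 in the recently evolved list and 0 in the others. Both were the same family, miR827, which stands in both lists (edgeR unadjusted p = 0.042). Its counts were 0 in the inflorescence, 15 in bud 1 and 1428 in bud 2, so its value rested on bud 2. DESeq2 called 1 nutrient family and 4 recently evolved families, all lower, and 0 in the others. Since it called 4 families lower in all, its nutrient family is also among the recently evolved ones.

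The third comparison concerned 21- and 22-nt sRNAs at annotated genes outside MIR and structural RNA loci. TAS transcripts are directed into phased tasiRNAs by miR173 or miR390 at all listed loci but TAS4. Of 8 listed TAS loci 7 were measured, and 4 fell while 0 rose in the edgeR test over all genes. These were TAS1B (chromosome 1, 18549204 to 18550042; log2 fold change −3.86 ± 0.85 SE, adjusted p = 0.00138), TAS1A (chromosome 2, 11721539 to 11722468; −2.92 ± 0.78, adjusted p = 0.00881), TAS2 (chromosome 2, 16539384 to 16540417; −2.59 ± 0.71, adjusted p = 0.0102) and TAS1C (chromosome 2, 16537288 to 16538277; −2.18 ± 0.68, adjusted p = 0.0261). Adjusted over the list alone 5 fell, TAS3B being added with −2.15, whereas TAS3 at −1.17 and TAS3C at −1.01 did not pass. In RPM TAS3, at 614, was level with bud 2 at 621, and TAS3C, at 26.96, lay between 55.6 and 13.03. TAS2 stood at 386 RPM in the inflorescence, 1540 in bud 1 and 1204 in bud 2. The TAS1A value rested on bud 1, since the inflorescence at 93.2 RPM was level with bud 2 at 91.7 and below bud 1 at 819, and without bud 1 its log2 fold change was −0.94. Without bud 2 that of TAS1C was −1.36. DESeq2 also called 4 TAS loci lower, but 0 passed when libraries were scaled by all genome-matched reads, where the log2 fold changes of those that fell were −3.11 at TAS1B, −2.29 at TAS1A, −1.83 at TAS2 and −1.35 at TAS1C. With a minimum of 50 reads 0 of 1647 genes passed in edgeR, so no TAS call remained. Antisense or overlapping genes share the TAS1B and TAS1C reads (AT1G07613 and AT2G39670).

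Few of the other listed secondary siRNA genes passed. Of 15 listed pentatricopeptide repeat (PPR) genes, a family of organellar RNA-binding proteins that miR161 and miR400 target, 12 were measured and 1 rose, AT1G62590, over all genes and adjusted over the list alone (2.30 ± 0.74, edgeR adjusted p = 0.0303). Its counts were 230, 35 and 10, and its log2 fold change was 3.68 without bud 1 and 1.59 without bud 2. Among 12 other phasiRNA genes 7 were measured. The disease resistance gene AT5G38850 rose (2.73 ± 0.72, edgeR adjusted p = 0.00871) and the resistance gene AT1G12290 fell (−4.41 ± 1.10, edgeR adjusted p = 0.00523). The latter rested on bud 2, with counts of 2, 1 and 55 in the inflorescence, bud 1 and bud 2, and without bud 2 its value was −0.04. Adjusted over the list alone 3 passed, the third being the auxin receptor gene TIR1 at 2.08 (adjusted p over all genes 0.0546), while AFB2, AFB3 and AGO1 did not, with 0.18, −0.66 and −0.14. The PPR and AT1G12290 calls were absent with DESeq2.

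Across all 5984 genes, 518 passed in edgeR, 93 higher and 425 lower in the inflorescence. Of the genes tested 58.1% were protein-coding and 32.4% pseudogenes. Of those that rose 48 (51.6%) were protein-coding and 33 (35.5%) pseudogenes, close to these shares, while of those that fell 394 (92.7%) were protein-coding and only 5 (1.18%) pseudogenes (Fisher's exact test, 2-sided, p = 2.8e-22 for pseudogenes among higher against lower genes, which are not independent). The largest increases under the rule for named genes were at the pseudogene AT4G06494 (chromosome 4, 3133152 to 3133586; 5.46 ± 0.93, edgeR adjusted p = 9.6e-06), at PAL4, a phenylalanine ammonia-lyase of the phenylpropanoid pathway (chromosome 3, 3203988 to 3208135; 4.95 ± 0.79, edgeR adjusted p = 1.9e-06), at AT5G53610 (4.52), at the pseudogene AT2G11730 (4.16) and at AT1G80220 (4.10). PAL4 had 756 reads in the inflorescence and 11 and 15 in the buds. The largest decreases were at AT4G10800 with 0, 6 and 134 reads and at the long noncoding RNA AT5G15022 with 0, 5 and 129. Against a floor of 3 counts in the inflorescence library these were at least 37.3-fold and at least 35.6-fold lower, but without bud 2 only 4.59-fold and 3.82-fold. VSP1, a jasmonate-induced storage protein, followed (−6.44 ± 1.10; counts 7, 126 and 608; −4.80 without bud 2), then AT3G50400 (−5.97; counts 2, 101 and 28; −3.38 without bud 1) and TGG2, a myrosinase that hydrolyses glucosinolates (−5.78; counts 2, 33 and 103; −3.95 without bud 2). Without bud 2, AT4G06494 stood at 4.28 and AT1G80220 at 3.17. AT5G15022 overlaps 4 other annotated loci, so its reads cannot be assigned to it alone.

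The split of calls depended on the scaling and on the filter. Scaling by all genome-matched reads gave 198 genes, 123 higher and 75 lower, and moved the median log2 fold change of all genes from −0.20 to 0.57. Scaling by matched reads without structural RNA gave 421 genes, 135 higher and 286 lower, with a median of 0.10. Without a filter on low counts 77 genes passed, 55 higher and 22 lower, so that the majority turned. With a minimum of 50 reads 0 genes passed in edgeR, although 385 had an unadjusted p below 0.05, and DESeq2 called 89 at the usual minimum.

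Phasing at TAS loci was measured as the share of 21-nt reads in the leading register of 21 in each library. Without phasing 1 fixed register would hold 4.76%, and random draws at these read numbers put a median of 6.06% in the leading register for the inflorescence, 5.19% for bud 1 and 5.42% for bud 2. The observed medians over 7 loci were 42.0%, 60.0% and 56.7%. The draws placed each read independently, whereas copies of 1 sequence share a register. A single abundant siRNA therefore exceeds the drawn level without phasing, and at TAS1C 1 siRNA held 22999 of the 35148 reads of bud 2. These medians alone do not show phasing. At TAS1A the share was 42.7% (exact 95% interval 39.7 to 45.7) in the inflorescence, 88.4% (87.8 to 88.9) in bud 1 and 56.7% (54.5 to 59.0) in bud 2. At TAS1B it was 23.4% (19.4 to 27.7), 89.4% (88.7 to 90.1) and 58.4% (56.8 to 60.1), at TAS1C 44.4%, 60.0% and 79.3%, and at TAS2 40.5%, 62.1% and 48.6%. TAS3 stood at 42.0% between 47.8% and 27.2%, TAS3B at 28.01% between 21.98% and 30.9%, and TAS3C at 67.7% above 48.5% and 57.4%. The leading register was the same in every library at TAS1A, TAS1B and TAS3C only. In the register with the most reads over all libraries, TAS1C at 9.35% lay below both buds, at 60.0% and 79.3%, and TAS3B at 1.39% lay below 3.91% and 30.9%. In that register TAS2 at 40.5% lay between 62.1% and 28.8%, and TAS3 at 42.0% above 24.3% and 26.09%. The inflorescence was below both buds under both definitions at TAS1A, TAS1B and TAS1C alone. At TAS1C the register with the most reads was the leading one of both buds but not of the inflorescence, and at TAS3B that of bud 2 alone. The choice of register itself made a lower inflorescence share likely there. Only at TAS1A and TAS1B was a lower share found in a leading register common to all libraries. TAS4 had 2, 2 and 5 reads, too few for a share. Counted over distinct sequences the medians were 11.9%, 8.97% and 8.95%, against 8.78%, 7.66% and 7.86% in random draws, and the order of the tissues turned. The median 95th percentiles of those draws were 11.1%, 9.09% and 9.27%. Each draw was for 1 locus, so they set no bar for a median over 7 loci. Single loci past the 95th percentile of their own draws were TAS1A, TAS1B, TAS1C, TAS2 and TAS3C in the inflorescence. In bud 1 they were TAS1B, TAS2, TAS3 and TAS3C, and in bud 2 TAS1A and TAS1B. The remaining loci were not past it, and the number of loci was not adjusted for.

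**Figure D4:**
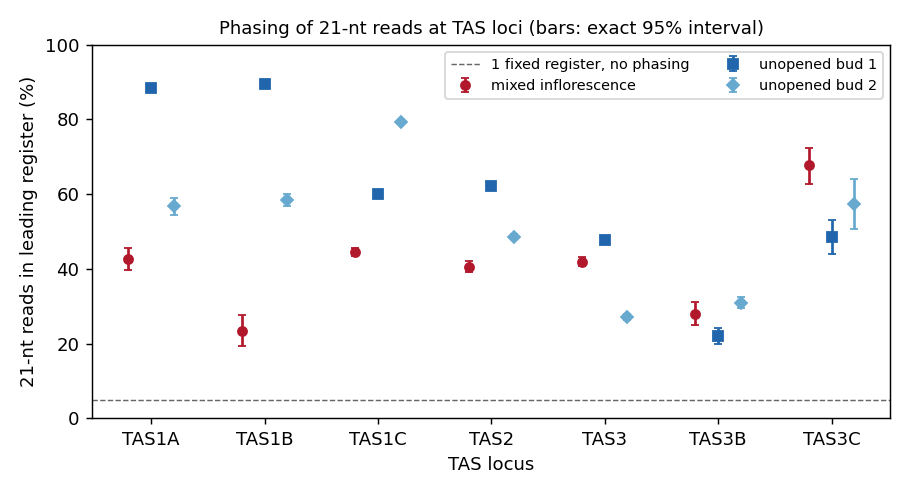
Share of 21-nt reads in the leading register (percent, vertical axis) at 7 TAS loci, 1 point per library with exact 95% intervals for counting error, and the level of 1 fixed register without phasing as a dashed line. At TAS1A and TAS1B, where the libraries share their leading register, the mixed inflorescence lies below both buds, while the leading register of the inflorescence at TAS1C is not that of the buds.

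The fourth comparison concerned 24-nt sRNAs at annotated genes. Strand was not examined for 24-nt reads, at genes or in bins, so whether those at a given locus were siRNAs was not tested. Of 6921 genes, 571 passed in edgeR, 211 higher and 360 lower in the inflorescence. Pseudogenes made up 99 of the 211 that rose (46.9%) and 36 of the 360 that fell (Fisher's exact test, 2-sided, p = 7.1e-23, genes not being independent), and protein-coding genes 82 (38.9%) and 241 (66.9%). Among the genes tested these classes took 45.8% and 41.5%, so it was the genes that fell that departed from the tested set. The largest increases were at the noncoding RNA AT2G09610, inside AT2G45380 (chromosome 2, 18702738 to 18703101; 4.46 ± 0.57, edgeR adjusted p = 0.00036), at AT4G02785 (chromosome 4, 644807 to 645929; 4.11 ± 0.51, edgeR adjusted p = 0.000323), at AT3G07135 (4.01), at AT5G53610 (3.92) and at GH9C3, an endoglucanase of the glycosyl hydrolase 9 family (chromosome 4, 6747234 to 6751536; 3.81 ± 0.47, edgeR adjusted p = 0.000323). GH9C3 had 5979 reads in the inflorescence and 253 and 283 in the buds. AT5G53610 also rose in 21- and 22-nt sRNAs, and AT3G50400 fell in both classes.

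The largest decreases were at BGLU18, a beta-glucosidase of ER bodies that releases abscisic acid from its glucose ester (−5.85 ± 0.86, edgeR adjusted p = 0.00123), at AT2G10557 (−5.14), at FBP, a fructose-1,6-bisphosphatase (−4.98 ± 1.20, edgeR adjusted p = 0.016), at AT3G50400 (−4.61) and at AT1G21835 (−4.51). FBP had 21 reads in the inflorescence, 31 in bud 1 and 956 in bud 2, and without bud 2 its log2 fold change was −1.38. Without bud 2 BGLU18 stood at −4.08, AT1G21835 at −2.45, AT5G53610 at 2.73, AT2G09610 at 3.82 and AT3G07135 at 3.10, and without bud 1 AT3G50400 at −3.60, AT5G53610 at 5.17 and AT2G09610 at 5.14. AT2G10557 overlaps AT2G10556, and its value turned to 0.32 when reads with several genome matches were counted.

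Of the TAS loci 6 had enough 24-nt reads, and TAS1B (−3.03) and TAS2 (−3.66; −2.67 without bud 2) fell, with 5 lower when adjusted over the list alone. Of the PPR genes 4 were measured and 0 passed, in edgeR or DESeq2, over all genes or adjusted over the list alone, with none below an unadjusted p of 0.05. Of the other phasiRNA genes 4 were measured, and AT1G12290, with 0, 4 and 51 reads that came mostly from bud 2, fell over all genes and adjusted over the list alone. Scaling by all genome-matched reads gave 335 genes, 230 higher and 105 lower, with the median of all genes at 0.41 instead of −0.10, and testing without a filter on low counts gave 582, 339 higher and 243 lower. Counting reads at several genome places by weight gave 0 calls in edgeR, with 1975 unadjusted p below 0.05, and DESeq2 on reads with 1 place called 231.

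The last comparison took 24-nt sRNAs in 1-kb bins of the nuclear genome, independent of gene models. The 1% of bins with the most reads held 58.4% of 24-nt reads in the inflorescence, 61.1% in bud 1 and 61.7% in bud 2, and gene-poor windows, taken as pericentromeric, held 41.8%, 39.5% and 39.7%. Of 26813 bins 2303 passed in edgeR, 881 higher and 1422 lower in the inflorescence. Gene-poor windows held 518 (58.8%) of the bins that rose, 450 (31.6%) of those that fell and 59.1% of bins tested. The largest increases were on chromosome 4 at 10992001 to 10993000, over the noncoding RNA AT4G20362 and RABE1b (5.53 ± 0.76, edgeR adjusted p = 0.00563), on chromosome 1 at 12062001 to 12063000 with no annotated gene (5.20 ± 0.70), and on chromosome 1 at 26757001 to 26758000 in AT1G70960 (4.98 ± 0.65). The first had 1344 reads in the inflorescence and 31 and 12 in the buds. It stood at 6.51 without bud 1 and 4.80 without bud 2, and the second at 5.98 and 4.65. The largest decreases had 0 inflorescence reads: the bin in FAR7, a fatty acyl-CoA reductase (chromosome 5, 7430001 to 7431000; 43 reads in bud 1; at least 38.7-fold lower, 21.3-fold without bud 2), in AT1G10400 (chromosome 1, 3414001 to 3415000; at least 32.8-fold lower, 19.8-fold without bud 2), and at the noncoding RNA AT4G26255 (chromosome 4, 13296001 to 13297000; at least 26.2-fold lower, 8.90-fold without bud 2). Bins that rose had a median GC content of 38.0% and bins that fell 28.5%, against 35.1% for those not called.

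The count of bins moved with scaling and with correction for GC. Scaling by all genome-matched reads gave 1275 bins, 586 higher and 689 lower, and scaling without structural RNA gave 3941, 790 higher and 3151 lower, with medians of all bins at 0.09 and −0.39 instead of −0.10. Removing each library's trend with GC content gave 1443 bins, 909 higher and 534 lower.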

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

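Reads outside the matched range of 18 to 28 nt, and reads of that range without an exact genome match, entered no comparison. Their shares are listed for that reason alone, and no control library was at hand to set them against. The comparison with the genome at 1 or 2 mismatches and the origins of the longer reads were chosen only after these shares were seen. No explanation was tested for any of these values.

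Reads longer than 28 nt made up 1.29% of the inflorescence library, 0.133% of bud 1 and 4.92% of bud 2. Of these, 24.9%, 63.5% and 80.9% matched the genome exactly. Ribosomal RNA held 23.4% of the matched long reads in the inflorescence, 86.4% in bud 1 and 75.6% in bud 2. Transfer RNA held 39.6%, 4.80% and 11.5%, and the chloroplast genome 32.3%, 1.53% and 1.34%.

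Among 21-nt reads, 29.3% had no exact match in the inflorescence, 12.2% in bud 1 and 15.6% in bud 2. Among 24-nt reads the shares were 38.6%, 8.74% and 16.5%. Of the unmatched 24-nt reads, 47.5% in the inflorescence matched with up to 2 mismatches, against 90.6% in bud 1 and 95.8% in bud 2. For 21-nt reads these shares were 56.7%, 67.9% and 91.8%. Of the unmatched 24-nt reads, 79.3%, 72.3% and 53.7% were sequences seen once.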

How the results depend on the processing

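Scaling by matched reads without structural RNA, end-base weights and the GC correction were chosen after the data were seen. No paired analysis was possible because the groups share no replicate numbers in the labels. Leaving out a bud library leaves 1 against 1, so it gave fold changes and no test: 518 of 518 called 21- and 22-nt genes kept their sign in both, 571 and 569 of 571 called 24-nt genes and 2303 and 2301 of 2303 bins. These features had been called on both buds, with 0, 2 and 2 of them between the buds, so the kept signs follow from that selection. Where not stated, the cause was not tested.

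With DESeq2 the calls numbered 28 miRNAs, 8 families, 89 and 231 genes (21- and 22-nt, then 24-nt) and 1088 bins, and 0 miRNAs or families passed under any other setting. Scaling by all matched reads gave 198 and 335 genes and 1275 bins, and without structural RNA 3941 bins. Without a filter 77 genes of 21- and 22-nt sRNAs passed, 55 higher and 22 lower, with 26793 tested, and 582 of 24-nt sRNAs, 339 higher and 243 lower, against majorities of lower genes with the filter. A minimum of 50 reads gave 0 and 251 genes, with fewer tested. Weighting reads at several places gave 950 and 0 genes, and turned AT2G10557 from −5.14 to 0.32. The GC correction gave 1443 bins.

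The inflorescence share of 21-nt reads was 24.2% of matched reads, 24.7% without structural RNA, 11.2% of distinct sequences and 24.9% without sequences seen once. Bud 1 gave 7.48% of distinct sequences, and bud 2 7.39%, or 22.9% without structural RNA. The 24-nt share under the same 4 settings was 46.1%, 48.7%, 49.2% and 43.1% in the inflorescence. Without structural RNA and over distinct sequences it was 58.9% and 49.5% in bud 1 and 55.1% and 46.2% in bud 2. The median phased share was 40.5% in the inflorescence with a register common to the libraries, and over distinct sequences 11.9%, 8.97% and 8.95%.

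For 36 called features named here there were 301 values under other settings. Of these, 211 kept their call or, without a bud library, shifted by less than the main standard error. The rest were 56 past the threshold no longer, 33 fold changes that shifted by more without a bud library, and 1 reversed. For 10 abundant miRNAs 71 of 80 values stayed uncalled or shifted by less than that error, 5 passed and 4 shifted by more. Their standard errors were 3.87 to 7.19 log2 units, so the 71 do not show that these values were stable. Bud 1, with 11808921 reads, limits low counts most.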

Other observations

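The tests of counting error, of library scaling and of the difference between the arms of a precursor, and the limits to tasiRNAs with 1 genome place and to precursors with unshared sequences, were chosen only after the results they bear on were seen; the others were chosen before. The comparison meant to test scaling replaced 2 earlier forms, dropped because they ran on genes picked for their decrease. Single tasiRNAs also parted between the buds. At TAS1C the siRNA TTCTAAGTTCAACATATCGAC (chromosome 2, 16537816 to 16537836) had 394 reads in bud 1 and 22999 in bud 2, while TACAAGCGAATAGACCATTTA, in the same phase at 16537879 to 16537899, had 2453 and 28. In the inflorescence they had 1 and 55. Both were named after their values were seen.

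Mature miRNAs with at least 1000 bud reads differed between the bud libraries by up to 1400-fold in RPM of genome-matched reads, with 0.5 reads added. Counting error does not account for this, since these 48 miRNAs had a standard deviation of 4.73 of the log2 ratio between the buds. For 18 precursors whose 5′ and 3′ sequences each came from 1 MIR gene, the difference between the log2 ratios of the arms had a standard deviation of 5.63 (bootstrap 95% interval 3.86 to 6.88) against 0.98 from counting, which argues against different amounts of each precursor as the whole source. As a part of it they cannot be told apart from effects on single sequences, since the Pearson r of the arms was 0.21 over these few precursors (bootstrap 95% interval −0.17 to 0.57, permutation p = 0.394), and the −0.15 (−0.45 to 0.15) over the 41 planned pairs rests partly on sequences that mix the output of several precursors. Among 45 tasiRNAs with 1 genome place, which share a transcript within each of 5 TAS loci, the log2 ratio had a standard deviation of 3.40 about the locus median, against 0.34 from counting, so sequence-dependent capture during library preparation may underlie part of the scatter, while differences between the bud samples in stability or loading of single sRNAs stay open and untested.

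The 394 protein-coding genes with fewer 21- and 22-nt reads in the inflorescence had a median of 97.4% of their bud reads on the sense strand, over the 392 with at least 20 bud reads, against 65.2% for protein-coding genes not called and 56.4% for those that rose. Fragments of messenger RNA in the bud libraries are a candidate source of these reads, of which 21- and 22-nt lengths made up a median of 23.0% of those of 18 to 28 nt, against 19.6% for protein-coding genes not called and 18.2% if all lengths were alike. The named protein-coding decreases parted: VSP1 and TGG2 had 99.7% and 100% of their bud reads on the sense strand. AT4G10800 and AT3G50400 had 1.43% and 27.1%, so their bud reads were mostly antisense. A single scaling factor moves all genes of a library alike, so it cannot set protein-coding genes apart from pseudogenes. The median log2 fold change of all tested protein-coding genes minus that of pseudogenes was −2.08, and −2.27 without bud 1. Without bud 2 it was −1.11, no more than the 1.14 between the bud libraries themselves. Such a factor leaves the gap between the classes as it is, so the size of the gap does not test scaling. The gap itself cannot be told apart from variation between libraries. Scaling by all genome-matched reads moved the median of the 394 from −4.11 (median standard error 1.16) to −3.32 (1.25), nearer to 0, and 74 of them then passed, so the number of genes called depends on it. A difference in gene expression between the tissues stays open and untested.

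Bins of 24-nt sRNAs that differed were not removed by equal end-base composition, as 89.97% were still called with the same sign. Removing each library's trend with GC content left 43.9% called with the same sign, 58.9% of the higher and 34.6% of the lower bins, and all 2303 kept their sign. The median log2 fold change of the lower bins went from −3.28 to −2.62 and that of the higher bins from 2.45 to 2.49, so part of the decrease may follow GC content. GC bias and a difference between tissues that follows GC-poor sequence cannot be told apart for these bins, because all inflorescence reads come from 1 library. A difference between mixed-stage inflorescences and unopened buds stays open and untested.

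With 3 libraries there are 3 ways to set 1 against 2, too few for a share under 0.05. The real grouping gave 518 genes for 21- and 22-nt sRNAs, 571 for 24-nt sRNAs and 2303 bins, and the highest of the other groupings gave 5, 20 and 14. Those groupings took the inflorescence and a bud library as replicates, so their spread included the difference under test. Fewer calls follow whenever the inflorescence library is the most unlike, from whatever cause, so these numbers do not bear on the calls. For miRNAs and families every grouping gave 0, with up to 14 miRNAs and 5 families at an unadjusted p below 0.05 in the others and 8 and 4 in the real one.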
